A study of Danio rerio with 3 samples.

How the data were processed

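The deposited counts were filtered feature-barcode matrices of UMI counts, made with Cell Ranger 7.1.0 per the file headers. The processing notes of the authors name GRCz10, GRCz11 and danRer11 without giving a role for each, so no coordinates were used. CPM, ratios, clusters and doublet scores were computed here. The matrices held 27771 features, of which 9977 repeated the identifier as the name, and 7321 of these were given a symbol from the names table. The feature named ALX4 was read as alx4a from its identifier. A reference annotation of GRCz12tu was used only for the order of genes next to alx3 and alx4a. The demultiplexing summary was not used, and 0 further columns were used.

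Cells with fewer than 500 detected genes (493, 626 and 606) or more than 10% mitochondrial UMIs (622, 803 and 681) were removed, some for both reasons, which left 11840, 13496 and 15806 cells. Doublets were scored per library with Scrublet in Scanpy 1.11.5 at an expected rate of 6%, and cells scoring above 0.2 were removed (476, 634 and 685 cells, or 4.02%, 4.70% and 4.33%). That score was chosen after the automatic threshold had marked under 0.5% of cells in every library. The kept cells had a median mitochondrial share of 1.22%, 1.23% and 1.09%.

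All kept cells were clustered together without batch integration. Counts were scaled per cell and log-transformed, and 2000 variable genes were taken, without alx1, alx3, alx4a, alx4b and without mitochondrial, ribosomal and haemoglobin genes. 30 principal components (NumPy 2.4.6), 20 nearest neighbours (scikit-learn 1.9.0) and the Leiden method at resolution 1 with seed 1 (python-igraph 0.11.9) gave 30 clusters. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.

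Clusters were named from 22 marker classes (210 of 224 marker genes matched). A cluster took the class with most markers among its 10 leading genes. Ties, among them clusters 12, 16 and 23 with 0 markers among the 10, went to the class with the largest share of its markers at 2-fold, which was also required where fewer than 2 markers were among the 10. A named cluster needed at least 3 markers at 2-fold over other wild type cells with detection in at least 10% of cells and a pseudocount of 5 CPM. Clusters with under 20 wild type cells were named from all libraries. A cluster whose leading genes held as many markers of the other kind of cell, mesenchymal or not, stayed unnamed. Unnamed clusters counted as mesenchyme unless their median UMI number was under 1/3 of that of their libraries, as in cluster 15. This naming rule was settled after clusters had been seen: an earlier form put cluster 8 in the frontonasal class and failed the class check, and cluster 13 lost its name through the last condition. Cluster 4 was the largest of the frontonasal-like clusters in wild type and cluster 2 the largest in both mutants. 16 mesenchyme clusters outside the frontonasal-like class whose summed alx level in wild type was under 0.5 of the mesenchyme mean served as the clusters low in alx transcripts, a set chosen after values had been seen.

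UMIs were summed over the cells of a class in each library. Ratios are log2 of CPM plus 1, for genes with at least 50 UMIs in the 2 libraries together. Intervals are exact Poisson intervals for levels, exact conditional intervals for ratios and Clopper-Pearson intervals for shares, each at 95%. Intervals of list medians come from 1000 Poisson redraws of the counts. List members were counted as higher or lower past 1.5-fold. For single genes taken by the rule for named genes these words give the direction of the printed values. The 20 gene lists (341 of 353 genes matched) and the markers were written down before the data were examined. Each list median was ranked among 10000 random lists of equal size drawn from the 100 measured genes nearest in expression to each member. Given 1 library per genotype, no significance test of a difference between genotypes was made. The tests of explanations given last compare single values with set bounds.

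Genes named in the report were taken by a fixed rule, written down before the data were examined. In mesenchyme these were the 10 highest and 10 lowest log2 ratios among genes with at least 20 CPM in either library, with the same direction in at least 3 of 4 clusters that had 100 or more cells and 20 or more UMIs of the gene. In the frontonasal-like class they were the 8 highest and 8 lowest, to which up to 4 members per list with the largest ratios and the 4 alx genes were added. Mitochondrial, ribosomal, haemoglobin and unnamed clone genes were left out. Genes that lead a cluster of the class were not named as results, among them rbp4, NID1, pitx1, pitx3, myoc, fgl2a and ntn1a. The alx genes, which the rule always names, were the exception, and matn4 is printed only as a value moved by a setting. Shares of cells with a UMI were taken after thinning every cell to 3000 UMIs by sampling without replacement, with 6000 and no thinning as alternatives.

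Alternatives were fixed before the data were examined, except 9 added afterwards: clusters 8 and 13 added to the class (for shares and for expression), the low-UMI cluster counted as mesenchyme (likewise), leading genes left out of the clustering, clusters of the class weighted equally, doublet score under 0.1, ratios relative to the clusters low in alx transcripts, and the settings of the cluster 4 and 17 lists. The batch-balanced graph took 7 neighbours per library. A value was called the same where it lay within the counting interval of the main value, and reversed where the main value was past 1.5-fold and the other had the opposite sign. For single genes that interval was of the plain UMI ratio without the added 1 CPM, so a main value could lie outside it.

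In a self-test, counts for wild type and double mutant were drawn from the wild type mesenchyme profile, with 100 genes doubled and 100 halved in the double mutant. Of these, 86 and 76 passed 1.5-fold, as did 0 of 16915 unchanged genes. The draws held counting error only, so that 0 does not bear on differences between libraries. The interval held the true ratio for 189 of 200 altered genes, and 16 of 200 random lists of unchanged genes lay under percentile 5 or over 95. Those lists held genes drawn at random with independent counting error. The 16 therefore does not bear on lists whose genes vary together, such as those of a cell type.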

Results

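Cranial neural crest cells, which build much of the facial skeleton, were profiled by droplet-based single-cell RNA sequencing from zebrafish embryos at 48 hours post fertilization. The cells had been sorted for a fli1 EGFP and a sox10 mRFP reporter together. Wild type, alx3 mutant and alx3;alx4a double mutant embryos were each represented by 1 library from 33 pooled embryos. alx3 and alx4a encode homeodomain transcription factors of the frontonasal neural crest. The deposited libraries held 196892513, 237313808 and 256758068 UMIs, in the order wild type, alx3 mutant and double mutant, which is kept throughout. After filtering, 11364, 12862 and 15121 cells remained, with medians of 14961, 15735.5 and 14796 UMIs and 3179, 3355 and 3160 detected genes per cell. No genotype had a second library, so no difference given here has a replicate check. The 95% intervals cover counting error only. Both mutants were set against the same wild type library, so a deviation of that library appears in both comparisons.

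The targeted genes were read first in every library. In neural crest mesenchyme, alx3 (XM_005167111.4) was detected at 46.2 CPM (UMI counts scaled to equal library totals; 45.2 to 47.2) in wild type, 19.7 (19.1 to 20.3) in the alx3 mutant and 20.4 (19.8 to 21) in the double mutant. Against wild type these were log2 ratios of -1.19 and -1.14. alx4a (ENSDARG00000088332) stood at 95.1 (93.6 to 96.5), 86.0 (84.7 to 87.3) and 63.6 (62.5 to 64.7), with log2 ratios of -0.14 in the alx3 mutant and -0.57 in the double mutant. The members that were not targeted differed less: alx1 (ENSDARG00000062824) was at 16.0, 14.4 and 13.3 CPM and alx4b (ENSDARG00000074442) at 22.1, 23.8 and 18.8. Within the frontonasal-like clusters alx3 was at 188, 77.5 and 86.3, and alx4a at 366, 336 and 257. alx3 was lower in the clusters with few alx transcripts too, at 3.51 CPM in wild type and 1.52 in the alx3 mutant. Relative to these its log2 ratio in the alx3 mutant class was -0.43. That reference is near the floor, so the value does not show how much of the difference in the class was shared. Over mesenchyme and over the class as a whole, each targeted transcript was thus lower in every library labelled as its mutant, and in mesenchyme alx4a was lower in the double mutant than in the alx3 mutant (-0.43). Within cluster 2 alx4a was not lower, at 225, 269 and 288. The reads tag the 3' end of a transcript, which may lie outside the mutated part, so these levels check the labels only so far.

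**Figure D1:**
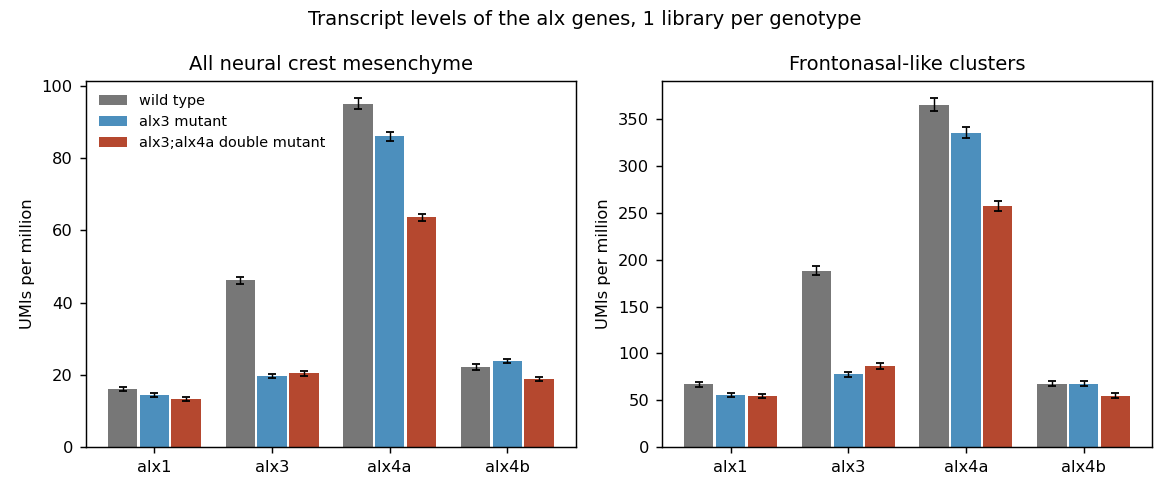
Levels of alx1, alx3, alx4a and alx4b in each library as CPM with Poisson 95% intervals, in all mesenchyme and in the frontonasal-like clusters. In the frontonasal-like clusters alx3 was at 188, 77.5 and 86.3 in wild type, alx3 mutant and double mutant.

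Which regions of the face the sorted cells came from was asked next. Clustering with the alx genes left out gave 30 clusters, of which 24 were neural crest mesenchyme (96.4%, 96.5% and 88.8% of kept cells). The lower double mutant value came from cluster 15, a shallow unnamed cluster left out of mesenchyme, and with mutant cells assigned to wild type clusters the shares were 98.6%, 98.6% and 98.8%. Clusters 2, 4, 9, 14 and 17 were frontonasal-like, led among others by pitx2, pax3a, lmx1ba and lmx1bb, and held 2853, 3028 and 2789 cells. They made up 26.1% (25.2 to 26.9) of wild type mesenchyme, 24.4% (23.6 to 25.2) of alx3 mutant mesenchyme and 20.8% (20.1 to 21.5) of double mutant mesenchyme. The 5 clusters did not move together: cluster 4 was the largest of them in wild type and cluster 2 in both mutants, cluster 9 was smaller only in the double mutant, and cluster 17 was larger in both mutants. The mix within the class thus differed between libraries, which bears on values within it. An alx gene was among the 10 leading genes of clusters 4 and 17 only. Cluster 9 (5.14%, 5.33% and 3.06% of mesenchyme) was led by lmx1ba, pitx3, aqp3b and myoc. The class may therefore hold more than 1 kind of mesenchyme, and its lower share in the double mutant need not be of 1 kind. Under this clustering the classes of the pharyngeal arches were more alike. Maxillary-like cells made up 15%, 15.8% and 15.7%, mandibular-like cells 24.7%, 24.7% and 25.9%, and hox-positive cells 12.7%, 13% and 12.7%. With mutant cells assigned to wild type clusters, mandibular-like cells made up 30.5%, 31.7% and 35.9%. That setting also assigned the shallow cells of cluster 15, and double mutant mesenchyme then held 14938 cells against 13424. Of the 1173 double mutant cells of cluster 15, 6 went to frontonasal-like clusters. The others can raise the share of an arch class there. At resolution 2 maxillary-like cells made up 17.9%, 19.5% and 20.4%. Both shares were higher in the double mutant than in wild type under each other setting. Chondrocyte-like cells (clusters 8 and 24) made up 5.87%, 6.36% and 7.18%, but this order was turned round under 7 of 9 other settings, as at resolution 0.5 with 2.31%, 1.99% and 1.39%. No direction is therefore given for this share. Clusters 24 and 8 went opposite ways under the main clustering. Cluster 24 made up 2.34% (2.06 to 2.64), 1.99% (1.75 to 2.25) and 1.40% (1.21 to 1.61) of mesenchyme, and cluster 8 made up 3.53%, 4.37% and 5.78%. Outside the mesenchyme, neuron-like (1.66%, 1.42% and 1.52% of kept cells), pericyte-like (0.968%, 1.08% and 0.893%) and epithelium-like cells (0.880%, 0.435% and 1.03%) were minor.

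The double mutant had the lowest frontonasal-like share under each of the 11 other settings. At resolution 0.5 the shares were 14.7%, 15.2% and 11.3%, with the alx3 mutant above wild type, and without a cell filter they were 17.1%, 14.6% and 13.4%. Clusters of each other clustering were named anew by the same rule, so which cells count as frontonasal-like can differ too. Cluster 8, named from chondrocyte markers and counted among the chondrocyte-like cells, and the unnamed cluster 13 also held alx transcripts, and made up 3.53%, 4.37% and 5.78% and 3.46%, 3.31% and 3.78% of mesenchyme. With both added the shares were 33.1%, 32.1% and 30.3%, so the double mutant stood less far below wild type. With the leading genes of the frontonasal-like clusters also left out of the clustering, the shares were 22.5%, 21.8% and 18.7%. Sorting and loading were done library by library, so these shares describe the libraries.

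**Figure D2:**
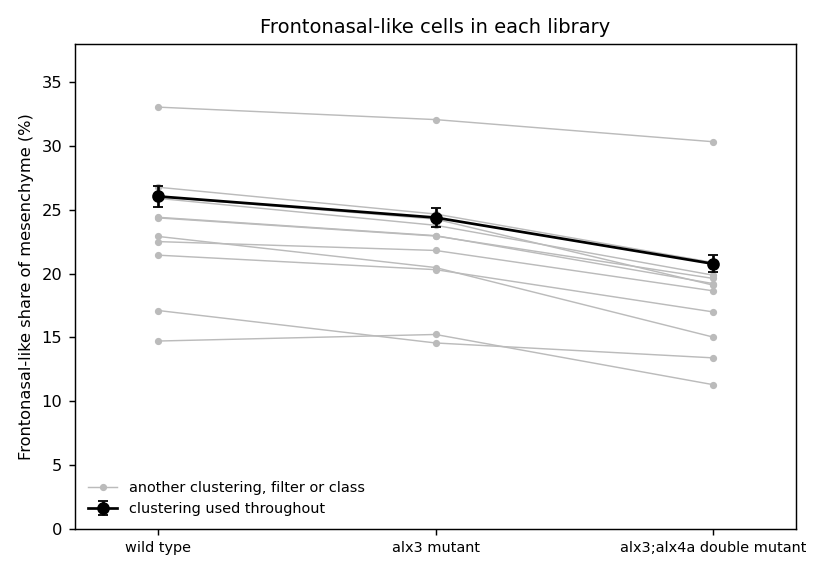
Share of mesenchyme cells in frontonasal-like clusters in each library with its 95% interval (black) and under 11 other settings (grey). The main shares were 26.1%, 24.4% and 20.8%.

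The comparison of alx3 mutant with wild type asks what is altered when alx3 alone is mutated. In the mutant mesenchyme the cartilage list had a median below 0 and the G1/S list of DNA replication genes a median above 0, mostly through differences within 1.5-fold. The cartilage list had a median log2 ratio of -0.29 (-0.31 to -0.25) over 27 measured members, at percentile 0 of 10000 expression-matched random lists, with 2 members lower by more than 1.5-fold. col9a3, a cartilage collagen, was at 59.3 against 87.0 CPM, col1a1b, a type I collagen, at 166 against 252, and the corneal and tendon proteoglycan gene kera at 10.0 against 15.9. The replication clamp gene pcna was at 851 against 679 and the helicase gene mcm7 at 58.4 against 44.5, with the G1/S list at a median of 0.20 (percentile 99.4) and 0 of 16 members past 1.5-fold. The Bmp and Tgf-beta list lay at -0.14 and the stress list at 0.14, with 3 of 27 members higher and atf3 lower (21 against 40.4).

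Several single genes of the alx3 mutant differed more widely than the lists did. phb2a, which encodes a mitochondrial prohibitin, was at 75.9 against 29.1 CPM (log2 1.35; ratio 2.52 to 2.69) and higher in 24 of 24 clusters. The heat shock gene hsp90aa1.2 was at 29.1 against 14.8, the tubulin gene tuba1a at 60.9 against 34.2 and the histone gene hist1h2a8 at 40.4 against 22.3, while prrg1, pitpnaa, hspa4a, ftsj3, ss18l2 and znf346 were higher by log2 0.67 to 0.86. On the lower side, dap1b was at 50.2 against 169 (log2 -1.73), the linker histone gene h1-10 at 207 against 596 (-1.52), the glypican gene gpc6a at 39.9 against 102 (-1.34) and igfbp1a at 9.57 against 28.5 (-1.48). The transporter gene slc1a4 (13.5 against 31.2), lxn (18.8 against 39.7) and mxra8b (19.5 against 38.9) were also lower. In the 16 mesenchyme clusters low in alx transcripts, sox10, the gene of the sort reporter, was at 34.7, 22.1 and 20 CPM.

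Within the frontonasal-like clusters the alx3 mutant had less bmp5 and rspo2, genes of the Bmp and Wnt pathways, and somewhat more of 2 genes of the dorsal arches. bmp5 was at 27.1 against 56.0 CPM, rspo2 at 12.8 against 30.3 and the ventral arch gene msx1b at 114 against 190, whereas nr2f1a was at 83.2 against 56.7 and grem2b at 36.2 against 25.5. grem2b was equal without a cell filter and with doublets kept (0.01), a setting that also clustered the cells anew. The cause of that move was not tested. Among other frontonasal genes 0 of 14 passed 1.5-fold (median -0.12), although pax7b came near it at 34.4 against 52.0. The maxillary and dorsal arch list had a median of 0.20 (0.11 to 0.30; percentile 97.3) with 0 of 13 members past 1.5-fold, and the Dlx list 0.11 (-0.01 to 0.23) with 0 of 7. The keratin gene krt94 stood out at 31.9 against 1.76 (log2 3.58, or 2.45 with a pseudocount of 5 and 2.90 in cells holding an alx1 or alx4b UMI), while the keratin gene krt91 (6.48 against 23.5), clu (5.76 against 20.3) and SPOCK1 (7.48 against 23.1) were lower. Epithelium-like cells, a source of keratin transcripts, were 0.435% of kept cells against 0.880%.

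Other genes of the frontonasal-like clusters in the alx3 mutant had their difference in common with the rest of the face. Set against the ratio in the clusters low in alx transcripts, the log2 ratio of dap1b went from -1.65 to 0.12, that of h1-10 from -1.63 to -0.14, that of igfbp1a from -1.49 to -0.02 and that of phb2a from 1.47 to 0.14. The ratio of SPOCK1 went from -1.51 to -0.89 and that of CPNE8 (20.9 against 9.04) from 1.13 to 0.48. CPNE8 and phb2b (30.2 against 15.2) were higher in the class. sp5a (12.2 against 6.53) was higher too, foxf2a (90.2 against 61.4) stayed within 1.5-fold, and vegfaa (7.59 against 15), pfkfb4b (35.1 against 65.4) and dhrs3b (34.6 against 57.3) lower. The cartilage list was at -0.26 with 3 of 21 members lower, the ligament list at -0.23 with 3 of 13 lower, and the G1/S list at 0.29 with 1 of 15 higher.

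The comparison of double mutant with wild type asks what is altered when both alx3 and alx4a are mutated. In the frontonasal-like clusters of the double mutant, some transcription factor genes of the frontonasal region were lower, and some genes typical of the pharyngeal arches were higher. pax7b was at 21.4 against 52.0 CPM (log2 -1.24), pax7a at 120 against 183, tfap2b at 35.4 against 66.3 and tbx2b at 21.2 against 32.6. The list of other frontonasal genes had a median of -0.39 (-0.43 to -0.35; percentile 0.03) with 5 of 14 members lower and 0 higher, and in the clusters low in alx transcripts its median was -0.04. With the 5 clusters weighted equally it was -0.27. Some list members, among them pax7b and tfap2b, were also markers by which the class was named from wild type cells, which can favour lower mutant values. grem2b, which encodes a Bmp antagonist, was at 95.5 against 25.5 (log2 1.87; ratio 3.47 to 4.05), nr2f1a at 101 against 56.7 and the Wnt-responsive gene sp5a at 24.6 against 6.53. Values of grem2b, sp5a and the Dlx genes named next changed with how the cells were chosen and clustered.

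The Dlx list of arch identity genes had a median of 1.03 (0.84 to 1.13; percentile 100) in the double mutant class, with 5 of 7 members higher. dlx1a was at 12.6 against 4.02 CPM, dlx2a at 18.5 against 8.60, dlx5a at 37.3 against 16.7 and dlx6a at 13.4 against 5.43. Without a cell filter and with doublets kept, where cells were clustered anew and the class can differ in makeup, the median was -0.062. It was 0.54 with mutant cells assigned to wild type clusters, 0.63 with cells of doublet score under 0.1 and 0.15 in mesenchyme cells holding an alx1 or alx4b UMI. In those last cells grem2b was at 0.30 and sp5a at 0.59, and dlx1a, dlx2a, dlx5a and dlx6a were at 0.39, 0.10, 0.22 and 0.14. Those cells came from all mesenchyme (3252, 3808 and 3576 cells), the clusters low in alx transcripts included. Arch levels of these genes can therefore hide a difference of frontonasal cells among them. Without a cell filter and with doublets kept, dlx5a and dlx6a were at -0.09 and -0.10, dlx1a at 0.60 and grem2b at 0.95. grem2b was at 1.14 with assigned cells and 1.17 under the lower doublet score, and dlx1a at 0.51 with assigned cells. Cells with 2 or more Dlx UMIs after thinning to 3000 UMIs were 37, 79 and 129, or 1.37% (0.967 to 1.89), 2.73% (2.17 to 3.39) and 4.83% (4.05 to 5.71) of the class. In the same class the stress list had a median of 0.51 (0.37 to 0.56; percentile 100) with 10 of 24 members higher, among them fosab (116 against 65.9) and junbb (32.4 against 14.8). The stress list was also above wild type in the clusters low in alx transcripts (0.28), so a part of this difference was shared, and relative to these clusters junbb was at -0.24.

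The cartilage, bone and ligament lists had medians below 0 in the same double mutant cells, each with fewer than 0.5 of its members past 1.5-fold. The cartilage list lay at -0.43 with 7 of 21 members lower, the bone list at -0.52 with 5 of 12 lower and the ligament list at -0.50 with 5 of 13 lower. col2a1a was at 590 against 1245 CPM, col9a3 at 64.8 against 156, kera at 36.3 against 69.8 and the perichondrium gene tgfbi at 491 against 873, whereas the tendon factor gene scxa was at 42.1 against 25.3. Set against the clusters low in alx transcripts, the cartilage median was 0.19, with col9a3 at -0.02 and col2a1a at 0.16, so this difference was not particular to the frontonasal-like cells. bmp5 (23.2 against 56.0), rspo2 (13.7 against 30.3), msx1b (82.2 against 190) and msx3 (44.0 against 73.0) were lower, and bmp5 was nearer wild type (-0.58) in cells holding an alx1 or alx4b UMI.

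The zinc finger gene glis1b (17.8 against 87.0 CPM, log2 -2.22), the ephrin receptor gene EPHA3 (31.6 against 150, -2.21), the chemokine gene cxcl14 (5.76 against 29.3, -2.16) and ADGRL1 (4.41 against 22.1, -2.10) had the lowest ratios in the class among the genes compared. These had at least 20 CPM in either library, and unnamed clone genes and genes that lead a cluster of the class were left out. In cells holding an alx1 or alx4b UMI, EPHA3 was at -1.61, cxcl14 at -1.03 and ADGRL1 at -1.50. Relative to the clusters low in alx transcripts glis1b was at -1.27 and cxcl14 at -1.22, and without a cell filter and with doublets kept cxcl14 was at -1.51. On the higher side stood krt94 (33.3 against 1.76; log2 3.64, or 2.50 with a pseudocount of 5 and 2.97 in cells holding an alx1 or alx4b UMI), the T-box gene tbx18 (90.6 against 35.4), tmem88b (62.0 against 24), phb2a (69.3 against 22.4) and hsp90aa1.2 (29.2 against 10.7). The last 3 were nearer to wild type relative to the clusters low in alx transcripts, at 0.65, 0.15 and 0.60, and hsp90aa1.2 was at 0.77 without a cell filter and with doublets kept and at 2.15 with assigned cells.

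None of the remaining lists had more than 4 members past 1.5-fold in either direction in the double mutant class. The maxillary and dorsal arch list was at 0.23 with 2 of 13 members higher and 1 lower, the Hox list at 0.19 with hoxb3a at 14.9 against 10.2, and the ventral arch list at -0.24 with 3 of 19 lower and 1 higher. Notch genes were split, with 4 of 15 higher and 2 lower around -0.21, and Wnt genes likewise, with 3 of 22 higher and 3 lower around 0.04. The Forkhead and Hedgehog list was at -0.24 (foxp2 18.6 against 37.0, hhip 68.1 against 47.8), the retinoic acid list at -0.15 (dhrs3b 32.5 against 57.3), the Fgf list at -0.08 (etv4 30.3 against 20.1) and the Bmp and Tgf-beta list at -0.29 with 3 of 23 lower and 2 higher. G1/S genes were at 0.28 with 0 of 15 past 1.5-fold (dut 414 against 282) and G2/M genes at -0.12 (CENPF 119 against 156). The p53 list stood at -0.19 (sesn1 21.9 against 33.3), the hypoxia and glycolysis list at 0.07 (hk2 17 against 10.9) and the alx family at -0.40 with 1 of 4 past 1.5-fold.

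**Figure D3:**
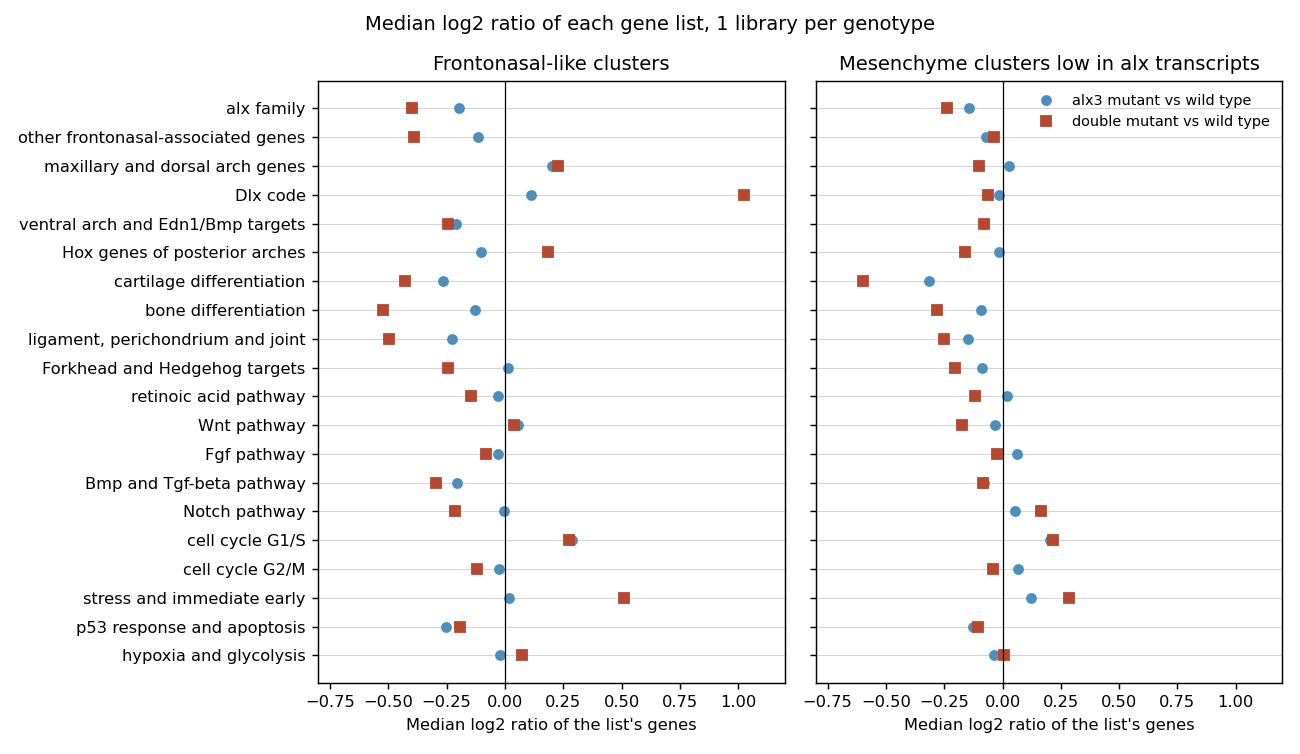
Median log2 ratio of the 20 gene lists in alx3 mutant (circles) and double mutant (squares) over wild type, in the frontonasal-like clusters and in the mesenchyme clusters low in alx transcripts. In the double mutant the Dlx list was at 1.03 in the first and -0.06 in the second.

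Across all mesenchyme of the double mutant, cartilage genes were the lowest list, and the stress and G1/S lists were the highest. The cartilage median was -0.51 (-0.54 to -0.49; percentile 0) with 11 of 27 members lower and 0 higher, with col9a3 at 38.3 against 87.0 CPM and col9a1a at 55.7 against 114. In the clusters low in alx transcripts it was -0.60 with 13 of 26 lower. The bone list was at -0.32 with 3 of 14 members lower and the ligament list at -0.28 with 2 of 14 lower, as in col1a1b (146 against 252) and kera (7.69 against 15.9), while col1a2 (432 against 630) and trps1 (196 against 278) stayed within 1.5-fold. The stress list was at 0.23 (0.17 to 0.28) with 10 of 28 members higher, and the G1/S list at 0.23 with pcna at 872 against 679. The other frontonasal list was at -0.26 with 5 of 14 lower, led by pax7b (3.73 against 9.68), while the Dlx (-0.04), maxillary and dorsal arch (-0.06) and ventral arch lists (-0.07) were near 0.

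Single genes of double mutant mesenchyme overlapped in kind with those of the alx3 mutant, which has the same wild type library as its base. phb2a (82.4 against 29.1; ratio 2.74 to 2.92), hsp90aa1.2 (28.1 against 14.8), hist1h2a8, prrg1 and pitpnaa (log2 0.84, 0.82 and 0.79) were higher again. So were the immediate early gene fosab (92.9 against 49.3), tmem88b (31.3 against 17), acaa2 (23.7 against 13.4) and NUAK2 (39.4 against 23.3). Lower were glis1b (6.11 against 23.5; ratio 0.244 to 0.276), igfbp1a (9.35 against 28.5), h1-10 (217 against 596), plecb (13 against 31.9) and dap1b (71.8 against 169).

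The comparison of double mutant with alx3 mutant asks what the added mutation of alx4a goes with. In the frontonasal-like clusters the Dlx list lay above its level in the alx3 mutant and the list of other frontonasal genes below it, and the wild type library has no part in these ratios. The other frontonasal list had a median of -0.26 (-0.30 to -0.22; percentile 0) with 2 of 14 members lower, among them pax7b at 21.4 against 34.4 CPM, while tfap2b (35.4 against 52.5) stayed within 1.5-fold. The Dlx list was at 0.96 (0.83 to 1.01) with 5 of 7 members higher, as in dlx5a (37.3 against 18.6) and dlx1a (12.6 against 5.82), and the Hox list at 0.37 (percentile 100) with 1 of 11 higher. That Hox difference did not hold without a cell filter and with doublets kept, where hoxb3a went from 0.63 to -0.015 and hoxa3a from 0.55 to -0.31. grem2b was at 95.5 against 36.2, sp5a at 24.6 against 12.2, tbx18 at 90.6 against 54.5 and the ventral arch gene hand2 at 17.9 against 10.4. In cells holding an alx1 or alx4b UMI, a set that includes arch cells, these were nearer to the alx3 mutant. There the Dlx median was 0.15, dlx5a 0.21, dlx1a 0.06, grem2b 0.20, sp5a 0.23 and hand2 -0.06. Arch levels can hide a difference of frontonasal cells in that set. With assigned cells grem2b was at 0.75 and dlx1a at 0.40, and under the lower doublet score grem2b was at 0.74. The Dlx median, which is the value of dlx5a there, was 0.000058 without a cell filter and with doublets kept.

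ZNF536 (30.7 against 82.9 CPM), flt4 (12.0 against 32.3), THRAP3 (12.7 against 33.1), the nuclear receptor gene roraa (10.0 against 24.1), glis1b (17.8 against 41.5) and the adhesion gene ncam1a (129 against 282) were lower in the double mutant class than in the alx3 mutant class. fgfr3 (125 against 222) and notch1b (27.0 against 49.4) were lower as well. The stress list had a median of 0.46 there, with 7 of 25 members higher, among them fosl1a at 14.4 against 6.66, or log2 1.01 and only 0.12 relative to the clusters low in alx transcripts. In all mesenchyme the double mutant had more of the immediate early genes junba (37.9 against 20.1; ratio 1.82 to 1.96), fosab (92.9 against 51.8) and atf3 (32.5 against 21), and of cbx7a (67.1 against 39.2), ptgr1.1 (184 against 117), cxcl18b (133 against 87.6) and cebpd (85.2 against 57.7). The cartilage median was again below 0 (-0.29; 6 of 27 members lower), with col9a3 at 38.3 against 59.3 and col9a1a at 55.7 against 85.9, and so were ZNF536 (17.7 against 30.1), the tendon gene mkxa (18 against 29.0) and EPHA3 (20.2 against 31.4).

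Whether single cells combined frontonasal and arch genes was asked in cells thinned to 3000 UMIs, which left out 368, 373 and 392 mesenchyme cells. alx1 or alx4b was found in 12.3%, 11.4% and 9.67% of mesenchyme cells (29.7%, 30.7% and 26.6% unthinned). Of these cells 5.38%, 6.05% and 7.22% had a dlx2a UMI, against 22.3%, 23.1% and 23.4% of other mesenchyme cells and 3.60%, 6.99% and 6.93% of neuron-like cells. For lhx6a the shares were 8.06%, 8.10% and 8.97%, for lhx8a 1.15%, 1.46% and 1.51%, for hand2 14.1%, 16.4% and 17.1%, and for any hox gene 15%, 17.4% and 18.8%. Among neuron-like cells, with median depths of 8988, 10139 and 11474.5 UMIs against 10599, 12399 and 12174 in the alx1 or alx4b cells, 2.16%, 4.90% and 4.46% had lhx6a, 12.2%, 7.69% and 7.43% had hand2 and 25.2%, 29.4% and 27.7% had a hox gene. The dlx2a shares of the alx1 or alx4b cells were thus near those of neuron-like cells, their hox shares lower, and their lhx6a and hand2 shares higher. Neuron-like cells may express some of these genes themselves, and cluster 28 among them held 2, 7 and 62 kept cells. They therefore do not settle the level of background. Each of the 5 shares was highest in the double mutant by a small margin. The alx1 or alx4b cells came from all mesenchyme, the clusters low in alx transcripts included. Those clusters held 1276 of 3885 alx4b UMIs and 196 of 2809 alx1 UMIs in wild type. In the double mutant they held 1559 of 4156 and 258 of 2939. A different mix of cells can thus raise these shares without frontonasal cells expressing arch genes.

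grem2b differed by cluster within the frontonasal-like class. In cluster 4 a grem2b UMI was found in 7.28% (5.55 to 9.35) of wild type cells, 15% (12.3 to 18.1) of alx3 mutant cells and 20.9% (17.9 to 24.1) of double mutant cells, and in 19.7%, 29.6% and 35.4% without thinning. In cluster 17 the shares were 5.10%, 9.64% and 13%, while in clusters 2 (3.81%, 2.74% and 4.73%) and 9 (2.76%, 3.78% and 4.25%) they were near those of neuron-like cells (4.32%, 4.2% and 6.44%). Median depths were 9205, 10767.5 and 11079 UMIs in cluster 4 and 8988, 10139 and 11474.5 in neuron-like cells, so depth alone does not set cluster 4 apart.

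**Figure D4:**
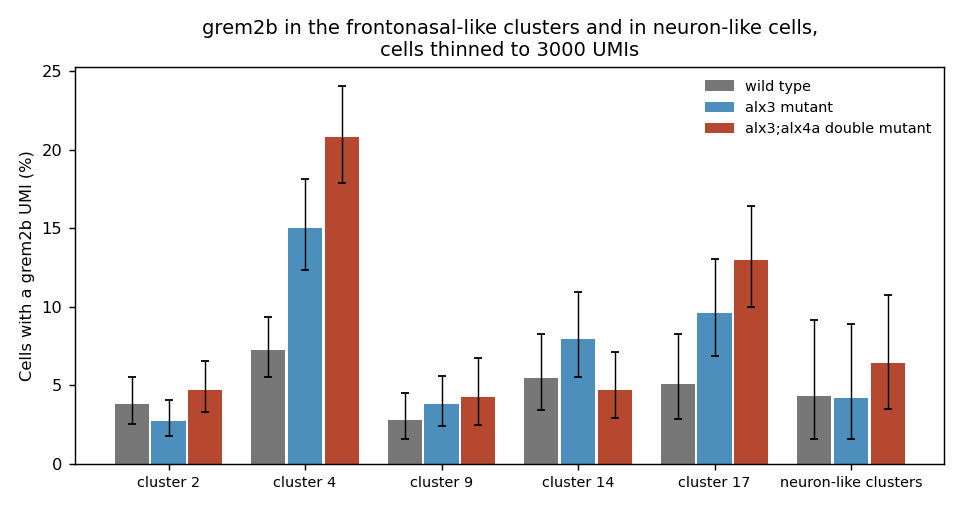
Share of cells with a grem2b UMI after thinning to 3000 UMIs, in each frontonasal-like cluster and in neuron-like cells, with 95% intervals. In cluster 4 the shares were 7.28%, 15% and 20.9%.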

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

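Both shares given here were singled out because a cluster of 1 mutant library has next to no wild type cells, and no test was chosen for them before or after they were seen. Cluster 15 held 10, 62 and 1173 cells of wild type, alx3 mutant and double mutant, or 0.0880%, 0.482% and 7.76% (7.34 to 8.20) of kept cells. Its cells were shallow, with a median of 3674 UMIs in the double mutant against 15487.5 in its mesenchyme. They carried twist1a (376 against 273 CPM in double mutant mesenchyme) and alx4a (61.1 against 63.6), with much gpc6a (559 against 63.6), and their mitochondrial share was 1.19% against 1.07%. Under the batch-balanced graph a cluster of like size and depth (23, 83 and 1108 cells) was named skeletal muscle-like, so the kind of these cells was left open. With 1 library per genotype, a cluster made mostly of 1 library was not taken as a cell state of the genotype.

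Cluster 28, neuron-like by elavl3, elavl4 and neurod1, held 2, 7 and 62 cells, or 0.0176%, 0.0544% and 0.410% (0.315 to 0.525) of kept cells. Together, neuron-like cells were 1.66%, 1.42% and 1.52%, so the double mutant had no larger share of neuron-like cells as a whole than wild type.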

How the results depend on the processing

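Each result had 1 library per genotype, so no setting replaces a replicate, and the cause of any move was not tested. Settings marked added were chosen after the data were examined. Of 168 class shares 57 stayed within the counting interval of the main value, of 1342 list medians 949 with 1 reversed, and of 5969 single gene ratios 3636 with 29 reversed. Only values past 1.5-fold under the main setting could count as reversed, so smaller values that changed sign are counted as moved. At a minimum of 200 UMIs single gene ratios are unchanged, yet 45 of 516 counted as moved, because their interval leaves out the added 1 CPM. Of the 29 reversed, 17 came from ratios relative to the clusters low in alx transcripts, which compare the class with other clusters. Of 60 co-detection shares 0 stayed, since thinning alters such a share by itself. No setting moved the median over all genes by more than 0.07.

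The frontonasal-like share of mesenchyme (26.1%, 24.4% and 20.8% in wild type, alx3 mutant and double mutant) was 14.7%, 15.2% and 11.3% at resolution 0.5 and 21.4%, 20.3% and 17% at resolution 2. It was 17.1%, 14.6% and 13.4% without a cell filter, 24.4%, 23.0% and 19.2% with the stricter filter, and 24.4%, 22.9% and 19.6% with alx genes kept in the clustering. With mutant cells assigned to wild type clusters it was 22.9%, 20.5% and 15%, and the balanced graph moved only the double mutant (19.9%). Assignment also placed the shallow cells of cluster 15, of which 6 of 1173 in the double mutant became frontonasal-like, and this can lower that share. Among added settings, leaving out the leading genes gave 22.5%, 21.8% and 18.7%, adding clusters 8 and 13 gave 33.1%, 32.1% and 30.3%, and counting the low-UMI cluster as mesenchyme moved only the double mutant (19.1%).

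alx3 in mesenchyme, alx3 mutant over wild type (log2 -1.19), was -1.33 when thinned, -1.05 with a pseudocount of 5 and -1.17 in all kept cells. In the double mutant (-1.14) it was -1.08 with size factors, -1.33 thinned, -1.01 with a pseudocount of 5, -1.10 with assigned cells, -1.09 in all kept cells and -1.12 with the low-UMI cluster (added). alx4a, double mutant over wild type (-0.57), was -0.51 with size factors, -0.68 as a mean over cells, -0.66 thinned, -0.54 with a pseudocount of 5 and -0.50 with clusters weighted equally. Over the alx3 mutant (-0.43) it was -0.37 with size factors, -0.51 thinned and -0.39 with clusters weighted equally.

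The cartilage list in mesenchyme, double mutant over wild type (-0.51), was -0.45 with size factors, -0.59 as a mean over cells, -0.63 thinned, -0.44 with a pseudocount of 5, -0.57 with at least 200 UMIs, -0.49 with assigned cells, -0.49 in all kept cells and -0.42 with clusters weighted equally. The other frontonasal list in the class, double mutant over wild type (-0.39), was -0.32 with size factors, -0.32 without a cell filter and with doublets kept, -0.30 with assigned cells and -0.34 in cells with an alx1 or alx4b UMI. Among added settings it was -0.27 with clusters weighted equally, -0.49 with clusters 8 and 13 and -0.29 relative to the clusters low in alx transcripts.

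The Dlx list in the class, alx3 mutant over wild type (0.11), was -0.13 with assigned cells. In the double mutant over wild type (1.03) it was 0.65 thinned, 0.79 with a pseudocount of 5, -0.062 without a cell filter and with doublets kept, 0.54 with assigned cells, 0.15 in cells with an alx1 or alx4b UMI and 0.63 with doublet score under 0.1 (added). Over the alx3 mutant (0.96) it was 1.04 with size factors, 0.63 as a mean over cells, 0.53 thinned, 0.71 with a pseudocount of 5, 0.000058 without a cell filter and with doublets kept, 0.64 with assigned cells and 0.15 in cells with an alx1 or alx4b UMI. The added settings gave 0.82 with clusters weighted equally, 0.74 with clusters 8 and 13, 0.41 with doublet score under 0.1 and 1.02 relative to the clusters low in alx transcripts.

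Ratios relative to the clusters low in alx transcripts (added) divide the class level by theirs, so a change of sign leaves the class's own ratio as it was. These single genes of the class were counted as reversed there. In the alx3 mutant they were prrg1 -0.048, dap1b 0.12, matn4 0.11, hsp90aa1.2 -0.18, hsp70.3 -0.11 and cdkn1a 0.18. In the double mutant over wild type they were matn4 0.080, col2a1a 0.16, col11a2 0.38, fgfr3 0.047 and junbb -0.24. Over the alx3 mutant they were fosab -0.022, junba -0.17, col2a1a 0.083, col9a2 0.082, col9a3 0.12 and col9a1a 0.17. In cells with an alx1 or alx4b UMI, cyp26a1 in the alx3 mutant was -0.16, sfrp5 and id2b in the double mutant over wild type -0.034 and -0.0019, and hand2, sfrp5 and hsp70.3 over the alx3 mutant -0.060, -0.13 and -0.042. Without a cell filter and with doublets kept, fgf3 in the alx3 mutant was -0.39, dlx5a and dlx6a in the double mutant over wild type -0.086 and -0.10, and dlx4a and hoxb3a over the alx3 mutant -0.030 and -0.015. With assigned cells id2b in the double mutant over wild type was -0.019.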

Other observations

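Of what follows, the cluster 4 and 17 lists, the 3 tests of the Dlx pattern and the test of equal levels in cluster 24 were chosen only after the result had been seen, while the other 4 tests were written before their values were made. Within the frontonasal-like class, cluster 4 had the largest difference in genes of the maxillary and dorsal arches in both mutants. Its maxillary and dorsal arch list had a median of 0.75 (0.54 to 0.95) in the alx3 mutant with 7 of 12 members higher, and 1.06 (0.91 to 1.23) in the double mutant with 7 of 11 higher, each at percentile 100. grem2b was at 41.5, 86.2 and 295 CPM in wild type, alx3 mutant and double mutant, nr2f1a at 53.4, 122 and 203, and jag1b at 22.0, 41.4 and 54.3. The frontonasal gene pax7b went the other way at 100, 28.9 and 30.3. With cells of doublet score under 0.1 the list medians were 0.56 and 1.05. The Dlx list of cluster 4 was at -0.08 in the alx3 mutant and 1.18 in the double mutant, and the Notch list of the double mutant at 1.02 with 8 of 12 members higher. Its higher members included her6 (116 against 49.5) but also dla (6.23 against 0.641) and dlb (12.3 against 0.769), 2 Notch ligand genes. Both were near the floor in wild type, so their ratios rest on few UMIs there, and the source of these transcripts was not tested.

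In maxillary and dorsal arch genes cluster 17 differed in the same direction to a smaller degree. Its maxillary and dorsal arch list was at 0.34 in the alx3 mutant and 0.46 in the double mutant, with 4 of 12 members higher in each, among them jag1b (17.5, 40.0 and 38.4) and hey1 (12.4, 22.4 and 29.2). Its Dlx list was above 0 too, at 0.34 (0.19 to 0.80) in the alx3 mutant, or 1.17 with doublet score under 0.1, and at 1.01 in the double mutant. Its alx family median was -0.45 in the alx3 mutant and -1.04 in the double mutant.

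The Dlx list was higher in the frontonasal-like class of the double mutant (1.03). A stress response shared by all cells stays open: in the clusters low in alx transcripts the stress list was at 0.28 and the Dlx list at -0.063, but there the CPM added in the class would raise the Dlx median by only 0.084 (wild type dlx5a 342 against 16.7), a condition added after the value was known. RNA of arch cells in frontonasal droplets may explain a part: the 30 most arch-enriched genes had a median of 0.47 (quartiles 0.20 and 0.67), below 0.5 of the Dlx value but not far enough below to count against it. Doublets may too, as cells with 2 or more Dlx UMIs had 1.34 times the UMIs of the others (15731 against 11783; doublet score 0.105 against 0.0461), between the bounds of 1.2 and 1.5, and this test replaced an earlier one after Dlx values per cluster had been seen. These and an effect of the alx mutations cannot be told apart, because 2 test values fell between their bounds, the stress test could not have seen the difference, and no second library exists.

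In the clusters low in alx transcripts, 39 of 4571 measured genes differed past 1.5-fold in both mutants, 11 higher and 28 lower, among them dap1b (157, 45.5 and 64.9 CPM), phb2a (30.9, 79.1 and 85.3) and the linker histone genes h1-10 (547, 194 and 200) and h1-0 (389, 208 and 178). Variants carried along with alx3 could explain some: 2 of 36 placed genes, prrg1 and cfp, or 5.56%, lay among the 200 nearest neighbours of alx3 on either side, against 1.56% of all measured genes. That share is over 3 times the background yet small, so it leaves linkage open for a few of the genes and not for most. A wild type library apart from both mutant libraries and an effect of alx3 loss cannot be told apart, since genotype and library are the same split here. The median size of 0.090 between the mutants, a count of genes in an earlier form, does not bear on this, because the genes were picked for differing from wild type in both.

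The cartilage list was lower in the clusters low in alx transcripts of the double mutant (-0.60). Fewer cells of chondrocyte-like cluster 24 at equal levels per cell is argued against, because the list was at -0.39 (-0.41 to -0.32) within that cluster. Cluster 24 made up 2.34%, 1.99% and 1.40% of mesenchyme. Fewer cells of cluster 24 may still explain a part, since without cluster 24 the median was -0.30 (-0.35 to -0.28), whose interval spans 0.5 of the full value. That interval condition was added after the first run, and without it the test would have counted against this explanation. Free RNA of chondrocytes may add to it, as neuron-like, pericyte-like and epithelium-like cells together had -0.19 (-0.24 to 0.03). In these cells col2a1a was at -0.36 but col9a1a at 0.62, against -1.04 and -0.68 in the clusters low in alx transcripts without cluster 24. In the clusters low in alx transcripts other than cluster 24, lower expression and a lower carry-over of cartilage RNA thus cannot be told apart. Inside both chondrocyte-like clusters, the presumed source of such free RNA, the list was lower too. It was at -0.39 in cluster 24 and -0.70 (-0.78 to -0.64) in cluster 8, with 1 library per genotype.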
